A study of Caenorhabditis elegans with 6 samples.

How the data were processed

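Polyadenylated RNA was sequenced from whole Caenorhabditis elegans worms of the strain CF512, which becomes sterile at high temperature. Per the labels' protocols, eggs were placed on RNAi bacteria and kept at 25 °C for 48 h, worms were collected on day 1 of adulthood, and stranded mRNA libraries were made from 1 µg of RNA. There were 6 libraries in 3 groups of 2, fed bacteria with the empty vector, with RNAi toward daf-2 or with RNAi toward cav-1. Per the series' design text, the experiment was done as 2 repeats, each holding 1 sample of every kind, and the sample titles give the repeat numbers.

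The authors deposited a single table with read counts per gene and library, headed as raw counts per sample, together with their own comparisons. Per the submitters' processing notes, the tools were bcl2fastq 2.15.0.4, cutadapt 1.7.1, TopHat2 2.0.13, Cufflinks 2.2.1 and DESeq2 1.10.1, with genome build WBcel235. Which of them counted the reads, the annotation release, the strand mode and the treatment of reads shared between genes are not given in the sources used here. The deposited log2 fold changes, p-values and adjusted p-values for the 3 comparisons came from the authors' DESeq2 run, per the submitters' processing notes, and are described here as deposited. The authors' normalised counts were not used here.

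The counts were whole numbers for 46748 genes, of which 494 (1.06%) had no value in any library and were left out, and 25210 had no count in any of the 6 libraries. Gene symbols came from the table, and missing symbols, among them 5 that a spreadsheet had turned into dates, were looked up by gene identifier in a reference list of names. Total counts ran from 25474328 to 32886440 per library. At this depth 10 counts correspond to between 0.304 and 0.393 CPM (counts scaled to the usual common library total), and counting error alone gives a coefficient of variation of 10% for a gene with 100 counts. Counting error covers neither library preparation nor differences between worms.

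A gene was tested if it had at least the CPM equivalent of 10 counts in a library of median size (0.348 CPM) in at least 2 libraries and at least 15 counts in total. This left 14378 genes with 99.96% of the counts. Libraries were scaled by TMM factors (30% of log ratios and 5% of mean levels trimmed), which ran from 0.922 to 1.04. The values tested were log2 of the scaled CPM plus a pseudocount of 1. Group means were compared by limma-trend (R 4.3.3, limma 3.58.1) fitted to all 6 libraries, with 3 contrasts, 2-sided p-values, Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The groups share 1 estimate of the spread because 2 samples are too few to estimate it per group. The fit had 3 residual degrees of freedom and a prior of 4.54.

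The count-based test planned at the outset was not run, because the deposited count columns hold entries without a value and did not pass a check of their format as counts. The test used was the one planned for a table without raw counts. The count-based refit planned as an alternative was left out for the same reason.

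A second fit, with the repeat number as an additive block, was also planned at the outset. The repeat numbers were taken to pair the samples from the series' design text, before calls were compared. Across 14378 genes the deviations of same-numbered libraries from their group means correlated at 0.891 for empty vector with daf-2 RNAi, 0.807 for empty vector with cav-1 RNAi and 0.812 for daf-2 RNAi with cav-1 RNAi. The blocked fit had 2 residual degrees of freedom and a prior of 8.68. The unblocked fit called no gene in any contrast. Leading with the blocked fit was decided after that was seen, and both counts are given for each contrast.

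Both fits were tested on simulated data with 200 changed genes among 14378 and an assumed biological coefficient of variation of 10%. With repeats made to differ as in the data for daf-2 RNAi against empty vector, the unblocked fit recovered 0 of 66 genes changed 4-fold, and the blocked fit recovered 66 of 66 changed 4-fold, 67 of 67 changed 2-fold and 35 of 67 changed 1.5-fold, with 4.0% of its calls false. For cav-1 RNAi against empty vector the blocked fit recovered 66 of 66, 65 of 67 and 35 of 67 in the same order, with 4.60% of its calls false, and the unblocked fit recovered 0 at each size. Without a difference between repeats, both fits recovered 97.0% of genes changed 2-fold and 100% of those changed 4-fold in both comparisons. The simulation gave every group the same repeat difference and assumed 10% variation, so it does not show how many real changes were missed. In the data cyp-14A3 lay at -1.95 under cav-1 RNAi (SE 0.27) and was not called (adjusted p = 0.0879 with the block).

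The named genes followed a rule written at the outset. It took daf-2, cav-1 and cav-2, the 10 largest rises and the 10 largest falls per treatment among called genes with a mean of at least 5 CPM and the same direction in both repeats, 5 each way for the treatments compared with each other, up to 4 called members of each gene list, or 2 members with the smallest p where none was called, and genes called under both treatments. After the data were seen, the pairs of uncalled members were kept only for lists that passed their own test. Members named outside the rule are marked as chosen after their values were seen.

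The 35 gene lists were fixed before the data were examined, and 4 of their entries matched no gene in the table. They cover targets of the transcription factor DAF-16, insulin signalling and insulin-like peptides, the caveolin and stomatin family, sphingolipids, endocytosis, chaperones and stress responses, the proteasome, autophagy, detoxification enzymes, antimicrobial genes and C-type lectins, yolk, lipid and carbohydrate metabolism, ribosomes, mitochondria, collagens and moulting, small RNA pathways, histones, and markers of sperm, oocytes, early embryos, intestine, muscle, neurons and hypodermis. Each list was tested with limma's camera on the unblocked fit with a preset correlation of 0.01 between genes. Its p was adjusted over the 35 lists of a contrast, and the test was repeated with the correlation estimated from the data. The test with an estimated correlation has only the fit's residual degrees of freedom, 3 unblocked and 2 blocked, so few lists could pass it. Failing it therefore does not show that correlated genes explain a list. The pathogen response list under cav-1 RNAi had an estimated correlation of -0.0039, below the preset. Its adjusted p with the block still went from 2.56e-12 to 0.475. Other lists had estimates above the preset. They were 0.12 for the class 1 list, 0.55 for ribosomal protein, 0.65 for proteasome and 0.67 for oocyte and germline genes. If correlations of that size are real, camera p-values with the preset are too small for such lists. Members are counted as risen or fallen by the blocked fit, adjusted over all tested genes and adjusted over the list alone.

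The alternatives were median-of-ratios size factors and total-count scaling in place of TMM, no filter (21044 genes) or a filter of 5 CPM in at least 2 libraries (9617 genes), pseudocounts of 0.5 and 5, fits on the 4 libraries of a comparison, and each library left out in turn. For the lists they also included the rotation test fry. Alternatives chosen after the data were seen were voom weights, removal of a lowess trend (span 0.3) on log2 transcript length from each library, the block combined with each of the other settings, and list tests with size factors. Transcript lengths and positions came from Ensembl release 115, which uses the same build, and 14270 of the tested genes (99.2%) had a length. A lone sample in a leave-one-out fit was assumed to vary like the other groups, and those fits with the block had 1 residual degree of freedom.

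The treatment responses were compared by shared calls against the number expected if calls were independent, and by the correlation and covariance of log2 fold changes across genes against 100 simulated draws of unchanged groups sharing the empty vector libraries. Genes are not independent replicates, and no p-value was attached to those correlations. Intervals on list medians are 95% bootstrap intervals over 10000 resamples of the members. These intervals, and the exact interval on a share of genes, describe spread among genes and not between samples.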

Results

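The data were read counts per gene in 6 libraries of whole day 1 adult worms, 2 each for empty vector, daf-2 RNAi and cav-1 RNAi. daf-2 encodes the worm's insulin/IGF-1 receptor, and cav-1 encodes a caveolin, a coat protein of small membrane invaginations. Empty vector repeats 1 and 2 held 25474328 and 29462916 counts, daf-2 RNAi repeats 28033393 and 32886440, and cav-1 RNAi repeats 32495577 and 27999017. The series title gives its purpose as comparing the expression profiles of the treated and untreated worms.

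The repeats differed more than the treatments did. The first principal component, with 65.9% of the variance, put the 3 libraries of repeat 1 on one side and those of repeat 2 on the other, and the second, with 23.5%, separated daf-2 RNAi from the other groups. The pharyngeal myosin gene myo-1 was 4.21 higher in repeat 2 (log2, SE 0.23, n = 3 per repeat), while the 23 muscle markers together had a median difference of -0.29. Tested between repeats with the treatment as a term, 3622 genes were higher in repeat 2 and 4654 lower. The difference rose with transcript length, from a median log2 difference of -0.51 for genes of up to 500 nt to 1.66 for genes over 5000 nt, with Spearman's rho of 0.545 across 14270 genes. The share of counts from the 12 mitochondrially encoded genes was 3.90% and 0.432% in empty vector repeats 1 and 2, 3.76% and 1.66% under daf-2 RNAi, and 2.70% and 1.49% under cav-1 RNAi. The yolk protein genes took 4.31% and 7.55%, 4.23% and 4.24%, and 3.45% and 7.13% in the same order.

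**Figure D1:**
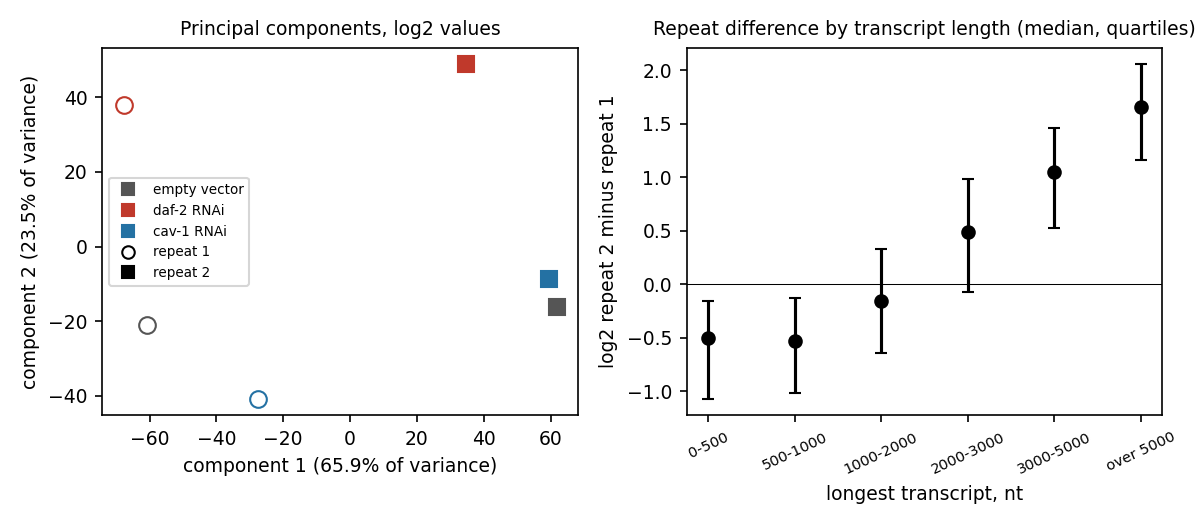
Left, the 6 libraries on the first and second principal components of log2 values, coloured by treatment, with open circles for repeat 1 and filled squares for repeat 2. Right, the median log2 difference between repeats (bars show quartiles) by longest transcript in nt, which goes from -0.51 in the shortest class to 1.66 in the longest.

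Both targeted genes were lower under their own RNAi. cav-1 (WBGene00000301, chromosome IV 9772510 to 9773559, plus strand, WBcel235, 2 exons) stood at 178 and 184 CPM in empty vector repeats 1 and 2 and at 6.13 and 1.84 CPM under cav-1 RNAi, a log2 fold change of -5.34 (SE 0.33, adjusted p = 9.43e-05 with the repeat block). It also fell under daf-2 RNAi, to 42.7 and 21.2 CPM, a log2 fold change of -2.55 (SE 0.33, adjusted p = 0.00191). daf-2 (WBGene00000898, chromosome III 2994514 to 3040846, minus strand, 19 exons) stood at 42.6 and 188 CPM in empty vector, 26.4 and 30.6 CPM under daf-2 RNAi, and 57.9 and 214 CPM under cav-1 RNAi. Its longest transcript has 7325 nt, and with the length trend removed its empty vector levels were 71.9 and 106 CPM. Its log2 fold change under daf-2 RNAi was -1.63 (SE 0.39, adjusted p = 0.0300), at -0.67 in repeat 1 and -2.58 in repeat 2, and under cav-1 RNAi 0.31 (adjusted p = 0.977). The second caveolin gene, cav-2 (WBGene00000302, chromosome V 13557104 to 13559922), was at 9.81 and 3.46 CPM in empty vector, with log2 fold changes of -0.08 under daf-2 RNAi and -0.17 under cav-1 RNAi (adjusted p = 0.879 and 0.982). Without the block none of these passed, and the smallest adjusted p was 0.521 for cav-1 under daf-2 RNAi. The daf-2 call was lost without empty vector 2 (-1.09, adjusted p = 0.113), without daf-2 RNAi 2 (-0.53, adjusted p = 0.641), without cav-1 RNAi 1 (-1.59, adjusted p = 0.0682) and with the length trend removed (-1.497, adjusted p = 0.0517), and without daf-2 RNAi 1 its value was -2.51. The cav-1 call under cav-1 RNAi was lost without cav-1 RNAi 1 (-5.77, adjusted p = 0.0567). Reads from an RNAi construct, if captured, would add to the count of its target.

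**Figure D2:**
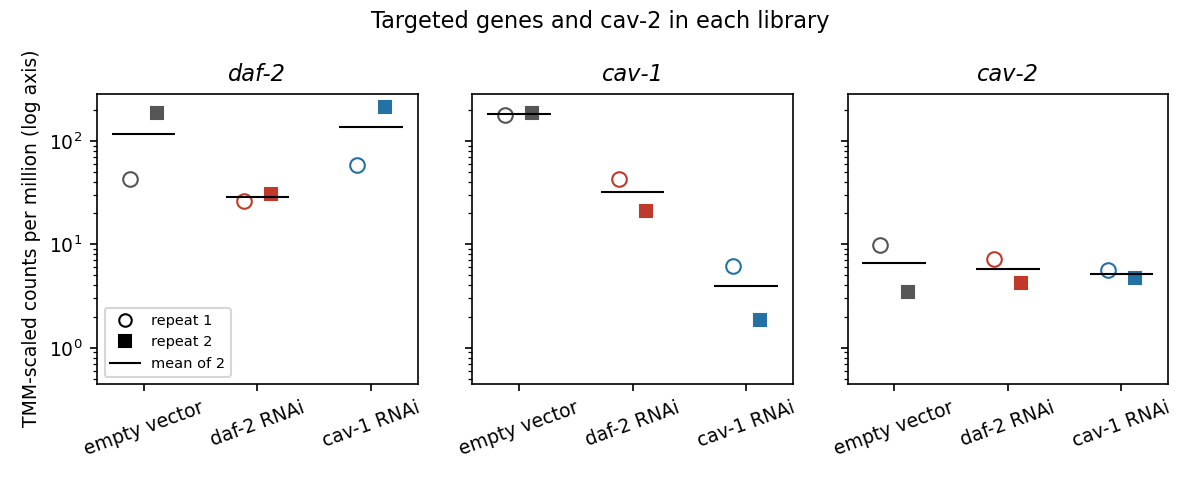
TMM-scaled CPM (log axis) of daf-2, cav-1 and cav-2 in each library, with open circles for repeat 1, filled squares for repeat 2 and a line at the mean of 2. cav-1 lies at 178 and 184 CPM in empty vector and at 6.13 and 1.84 CPM under cav-1 RNAi.

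Under daf-2 RNAi, compared with empty vector, 1070 genes changed with the repeat block, 620 higher and 450 lower. The largest rises were in D1086.9 (log2 4.90), ZK355.3 (4.84), ZK355.8 (4.05), H39E23.3 (3.82), Y51B9A.8 (3.67), F35E8.6 (3.40), clx-1 (3.37), T22F7.4 (3.27), dao-6 (3.06) and the lectin gene clec-76 (3.05). The largest falls were in C32H11.4 (-5.31), dod-23 (-4.23), clec-266 (-4.20), the glucosylceramidase gene gba-2 (-3.88), dod-24 (-3.86), dod-22 (-3.78), the cuticlin-like gene cutl-16 (-3.57), F08G5.6 (-3.52), the chitinase gene cht-1 (-3.07) and the homeobox gene ceh-43 (-2.95). Standard errors of these 20 ran from 0.24 (clec-76) to 0.48 (D1086.9), with adjusted p from 3.49e-05 to 0.00235 and n = 2 per group. ZK355.3 and ZK355.8 carry neighbouring sequence names, and reads could be divided between such genes.

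Genes of the DAF-16 class 1 list, which are known to be higher when insulin signalling is low, had a median of 0.85 (camera adjusted p = 0.000539, but adjusted p = 0.240 with an estimated correlation, and 0.0720 without and 0.0864 with the block in the fry test). Of 24 tested members 10 rose and 2 fell, and 15 rose and 5 fell when adjusted over the list alone. Among them dod-6 rose by 2.43, the superoxide dismutase gene sod-3 by 2.09, the metallothionein gene mtl-1 by 1.88 and the cytochrome P450 gene cyp-35B1 by 1.39. The 2 that fell, named after their values were seen, were the alcohol dehydrogenase gene sodh-1 (-1.20) and the metallothionein gene mtl-2 (-0.93). Of the 11 class 2 genes, known to be lower when insulin signalling is low, 4 fell, namely dod-23, dod-24, dod-22 and the yolk protein gene vit-5 (-2.35). dod-19 rose (1.05, named after its value was seen), and 5 fell and 1 rose adjusted over the list alone, with a median of -0.76 (adjusted p = 6.87e-05, and adjusted p = 0.240 with an estimated correlation), at -1.28 in repeat 1 and -0.25 in repeat 2. Of 26 insulin-like peptide genes 5 rose, namely ins-23 (2.52), ins-12 (1.699), ins-22 (1.26) and, named after their values were seen, ins-35 (2.56) and ins-10 (0.77). The mean level of ins-22 was 0.83 CPM, below the pseudocount of 1. ins-2 fell (-1.31), 8 rose and 2 fell over the list alone, and the median was 0.25 (adjusted p = 0.000539, and adjusted p = 0.240 with an estimated correlation). With the length trend removed that median was 0.06 and the list did not pass (adjusted p = 0.162). In the insulin/IGF-1 signalling pathway daf-2 alone passed among 22 genes (median -0.30, adjusted p = 0.414).

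Cuticle collagens formed the group with the smallest p. Of 108 tested collagens 31 rose and 2 fell, or 57 and 4 adjusted over the list alone, with a median of 0.59 (adjusted p = 4.64e-15, and adjusted p = 0.240 with an estimated correlation). Examples were col-94 (2.86), col-36 (2.53), col-98 (1.90) and col-103 (1.75). dpy-14 (-2.15) and col-135 (-1.14) fell and were named after their values were seen. Collagens form a family of close paralogs, so counts of single members are uncertain. In the moulting list wrt-10 fell (-2.21) among 20 genes, and 2 rose and 8 fell over the list alone (median -0.29, adjusted p = 0.0613, and 0.0492 with total-count scaling). Its adjusted p = 0.759 with an estimated correlation.

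Single genes for enzymes of detoxification and fat metabolism also changed. Of 59 UDP-glucuronosyltransferases 11 rose, among them ugt-13 (2.21) and ugt-8 (1.63), and ugt-53 (-1.89) and ugt-57 (-1.64) fell. The list's median was 0.49 (adjusted p = 0.000242, and adjusted p = 0.759 with an estimated correlation), with 16 and 2 over the list alone and repeat medians of 0.25 and 0.77. Of 39 glutathione S-transferases 5 rose and none fell by either adjustment, namely gst-3 (2.87), gst-19 (1.55), gst-29 (1.55), gst-4 (1.31) and, named after its value was seen, gst-39 (1.22). Their median was 0.30 (adjusted p = 0.000168, and adjusted p = 0.458 with an estimated correlation). Among 63 cytochrome P450 genes 8 rose, among them cyp-13A11 (2.07) and cyp-14A1 (2.00), and 6 fell, among them cyp-35A3 (-2.47) and cyp-14A3 (-1.90), with 11 and 6 over the list alone (median 0.08, adjusted p = 0.137). Of 39 genes of fatty acid desaturation, elongation and lipid storage 11 rose and none fell by either adjustment, including the fatty acid binding protein gene lbp-8 (2.63), the diacylglycerol acyltransferase gene dgat-2 (1.68), the elongase gene elo-6 (1.66) and hacd-1 (1.48). That list's median was 0.30 (adjusted p = 0.0173, and adjusted p = 0.240 with an estimated correlation). In the glyoxylate, trehalose and carbohydrate storage list the trehalose synthase gene tps-2 (1.29), the trehalase gene tre-4 (1.499) and the phosphoenolpyruvate carboxykinase gene pck-1 (0.91) rose and sodh-1 fell, out of 20, with 4 and 1 over the list alone (median 0.26, adjusted p = 0.120, 0.0230 with the repeat block and 0.0212 with the length trend removed). Its adjusted p with the block was 0.658 with an estimated correlation, and its repeat medians were 0.43 and 0.09.

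Antimicrobial and lectin genes went both ways. In the pathogen response list 3 of 33 genes rose and 7 fell, or 11 and 8 over the list alone. F08G5.6, T24B8.5 (-2.95), dod-22 and the thaumatin-like gene thn-1 (-2.40) fell, while clec-85 (1.68) rose, as did spp-12 (1.91) and spp-5 (0.79), named after their values were seen. The list's median was 0.17 and its mean -0.21, and the test pointed down (adjusted p = 0.795). Of 99 C-type lectins 10 rose and 7 fell, or 18 each way over the list alone, with clec-218 at -2.79. Their median was -0.02, and 0.05 with total-count scaling (adjusted p = 0.795). Among 19 heat shock and chaperone genes hsp-12.6 (1.104) and hsp-16.11 (1.00) rose and the near-identical pair F44E5.5 (-0.84) and F44E5.4 (-0.78) fell, with 4 and 2 over the list alone, a median of -0.28, a mean of 0.02 and a test pointing down (adjusted p = 0.763). sod-3 and gst-4 rose among 20 antioxidant genes (median 0.18, adjusted p = 0.0475, and adjusted p = 0.759 with an estimated correlation), and the list did not pass with size factors (median 0.11, adjusted p = 0.0634) or with the length trend removed (median 0.08, adjusted p = 0.0949). Neither the endoplasmic reticulum response (17 genes, median -0.22, adjusted p = 0.190) nor the mitochondrial unfolded protein response (10 genes, median -0.05, and 0.04 with total-count scaling, adjusted p = 0.860) had a member that passed.

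Of 9 tested early embryo genes 5 fell, namely tbx-37 (-0.92), sdz-28 (-1.92), pes-10 (-1.18), tbx-38 (-0.79) and, named after its value was seen, ceh-51 (-1.14). The list's median was -0.79 (adjusted p = 0.000169, and adjusted p = 0.240 with an estimated correlation). tbx-37 and tbx-38 had means of 0.65 and 0.53 CPM, below the pseudocount of 1, so their values rest on few counts. None of 30 oocyte and germline genes passed singly, with rme-2 at -0.65 and glh-2 at -0.62 (adjusted p = 0.114 and 0.124), and their median was -0.44 (adjusted p = 0.00467, and adjusted p = 0.759 with an estimated correlation). Only 5 of the 69 sperm genes had enough counts to be tested. None of these 5 passed, and 1 rose and 2 fell over the list alone (median -0.44, adjusted p = 0.414, and 0.0133 in the fry test with the block). vit-5 fell among 6 vitellogenins (median -0.39, adjusted p = 0.0231, and adjusted p = 0.759 with an estimated correlation), which share sequence. The vitellogenin median was 0.07 in repeat 1 and -0.88 in repeat 2, and the list did not pass with the length trend removed (median -0.24, adjusted p = 0.197) or with no filter (adjusted p = 0.272). The 24 neuron markers had a median of 0.55 with none passing, egl-3 at 0.86 and ida-1 at 0.81 (adjusted p = 0.0900 and 0.1001), and a list adjusted p of 0.000403. myo-1 rose (1.15) among 23 muscle markers (median 0.49, adjusted p = 0.00910). Both lists had an adjusted p = 0.240 with an estimated correlation. In the intestine list the gut esterase gene ges-1 rose (1.56) and the peptide transporter gene pept-1 (-1.69), mtl-2 and the acid phosphatase gene pho-1 (-1.28) fell, of 16 (median -0.29, adjusted p = 0.372). grd-10 rose (1.66) among 13 hypodermis markers (median -0.31, mean -0.01, adjusted p = 0.636).

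In the ribosomal protein, proteasome and small RNA lists no member passed. The 78 cytosolic ribosomal protein genes had a median of -0.27 (adjusted p = 0.000539), at -0.12 in repeat 1 and -0.43 in repeat 2, with rpl-11.1 at -0.57 and rpl-7A at -0.46. The 32 proteasome genes had a median of -0.33 (adjusted p = 0.00972), with rpn-2 at -0.45 and rpn-1 at -0.44, and the 28 small RNA genes a median of -0.46 (adjusted p = 0.0253), with ego-1 at -0.64 and ergo-1 at -0.58. These 3 lists had an adjusted p = 0.759 with an estimated correlation, and the small RNA list did not pass with the length trend removed (median -0.36, adjusted p = 0.0922). The 12 mitochondrially encoded genes had a median of 0.67 (adjusted p = 0.0253, and adjusted p = 0.799 with an estimated correlation), with nduo-4 at 1.099 and nduo-1 at 0.66, and medians of 0.00 in repeat 1 and 1.45 in repeat 2, where empty vector held 0.432% of its counts in these genes, and they did not pass with no filter (adjusted p = 0.0851). Of 29 histone genes the linker histone gene his-24 (-2.28) and his-72 (-0.86) fell and his-25 (1.17) rose, with a median of -0.32 (adjusted p = 0.00243, and adjusted p = 0.409 with an estimated correlation). The sphingomyelinase gene asm-3 fell (-2.08) among 20 sphingolipid genes (median 0.14, adjusted p = 0.763), asp-4 rose (0.89) among 27 autophagy and lysosome genes (median 0.15, adjusted p = 0.659), and cav-1 alone passed among 11 genes of the caveolin and stomatin family (median 0.07, mean -0.15, test pointing up, adjusted p = 0.860). None of 24 endocytosis genes (median -0.17, adjusted p = 0.397) or 35 nuclear oxidative phosphorylation genes (median 0.05, and -0.03 with size factors, adjusted p = 0.670) passed.

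Without the repeat block limma called 0 genes for daf-2 RNAi, with a smallest adjusted p of 0.215. At an unadjusted p under 0.05 lay 777 genes without the block and 3486 with it, against 719 if no gene changed. The repeat difference enters the residual of the unblocked fit, so the 777 cannot be read against 719. The blocked count moved from 1070 to 579 with the stricter filter (415 higher and 164 lower), to 1780 without empty vector 1, to 698 without daf-2 RNAi 2 and to 2197 without cav-1 RNAi 2. Without empty vector 2 the balance turned, with 309 higher and 511 lower. In the authors' deposited DESeq2 results 1320 genes passed at 0.05, 687 higher and 633 lower, and 973 of the 1070 genes were among them.

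**Figure D3:**
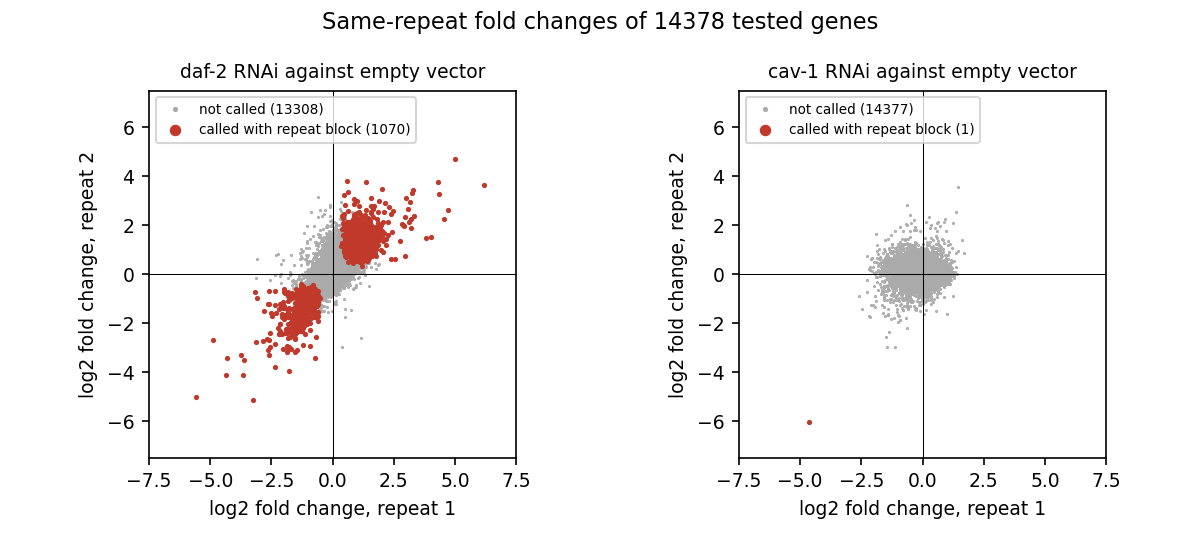
Log2 fold change against the empty vector library of the same repeat, repeat 1 on the horizontal and repeat 2 on the vertical axis, for the 14378 tested genes under daf-2 RNAi (left) and cav-1 RNAi (right). Red points passed with the repeat block, 1070 under daf-2 RNAi and 1 under cav-1 RNAi.

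Under cav-1 RNAi, compared with empty vector, cav-1 was the single gene that passed. Genes of the DAF-16 class 1 list, which lay higher under daf-2 RNAi, lay lower here. Their median was -0.56 over 24 members (adjusted p = 8.15e-13, and adjusted p = 0.190 with an estimated correlation), with 22 below 0, cyp-34A9 at -1.61 and sodh-1 at -1.48 (SE 0.27 each, adjusted p = 0.134 and 0.153). Adjusted over the list alone, 8 fell and none rose. The 33 pathogen response genes had a median of -0.58 (adjusted p = 3.59e-10, and adjusted p = 0.514 with an estimated correlation), with thn-1 at -1.87 and nlp-34 at -1.63 (adjusted p = 0.134 each), and 11 fell over the list alone. In both repeats the medians of the class 1 list (-0.53 and -0.68) and of the pathogen list (-0.51 and -0.49) were below 0.

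The 78 ribosomal protein genes had a median of -0.30 (adjusted p = 6.55e-09, and adjusted p = 0.824 with an estimated correlation), with rpl-29 at -0.52 and rps-2 at -0.47. The 63 cytochrome P450 genes had a median of -0.20 (adjusted p = 0.000867, and adjusted p = 0.827 with an estimated correlation), with cyp-14A3 at -1.95. The 19 heat shock genes had a median of -0.22 (adjusted p = 0.00888, and adjusted p = 0.514 with an estimated correlation), with hsp-70 at -0.78 and hsp-12.3 at -0.81, and did not pass with no filter (adjusted p = 0.455). The 108 collagens had a median of 0.07 (adjusted p = 0.00246, and adjusted p = 0.830 with an estimated correlation), with col-93 at 1.27 and col-94 at 1.51, and 3 rose and 1 fell over the list alone. The medians in repeats 1 and 2 were -0.26 and -0.00 for the cytochrome P450 genes, -0.11 and -0.48 for the ribosomal protein genes, -0.12 and -0.25 for the heat shock genes and 0.07 and 0.04 for the collagens. The class 2 list had a median of -0.10 (adjusted p = 0.912). With the repeat block the insulin pathway (median 0.12, adjusted p = 0.101 without and 0.0318 with the block), the endocytosis list (0.07, 0.126 and 0.0375) and the oocyte and germline list (0.09, 0.101 and 0.0375) passed as well, with blocked adjusted p = 0.692, 0.727 and 0.876 with an estimated correlation. The oocyte and germline median was 0.30 in repeat 1 and -0.15 in repeat 2. With the length trend removed the caveolin and stomatin family (median -0.13, adjusted p = 0.0358) and the glyoxylate list (-0.18, 0.0164) passed. The caveolin list holds cav-1 itself and was not tested without it, and before the removal these lists had an adjusted p = 0.830 and 0.874 with an estimated correlation. The other lists did not pass with or without the block, and the medians of the autophagy, antioxidant, glutathione S-transferase and fatty acid lists (-0.03, -0.03, -0.01 and -0.07) were above 0 with total-count scaling. The 12 mitochondrially encoded genes had medians of -0.29 in repeat 1 and 1.29 in repeat 2.

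Without the block limma called 0 genes for cav-1 RNAi, and with the block 1. At an unadjusted p under 0.05 lay 36 genes without the block and 573 with it, against 719 if no gene changed. For the reason given for daf-2 RNAi, the 36 cannot be read against 719. The blocked count depended on which libraries were used, with 82 from the 4 libraries of the comparison, 110 (61 higher and 49 lower) and 123 (4 higher and the rest lower) without empty vector 1 and 2, 75 and 73 without daf-2 RNAi 1 and 2, 0 without cav-1 RNAi 1 and 402 without cav-1 RNAi 2, and it was 6 with size factors and 2 with a pseudocount of 0.5 or with voom. In the authors' deposited DESeq2 results 81 genes passed at 0.05, 23 higher and 58 lower, and they included 3 class 1 genes, 8 pathogen response genes and 2 cytochrome P450 genes, all lower, and 4 collagens, 3 of them higher.

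**Figure D4:**
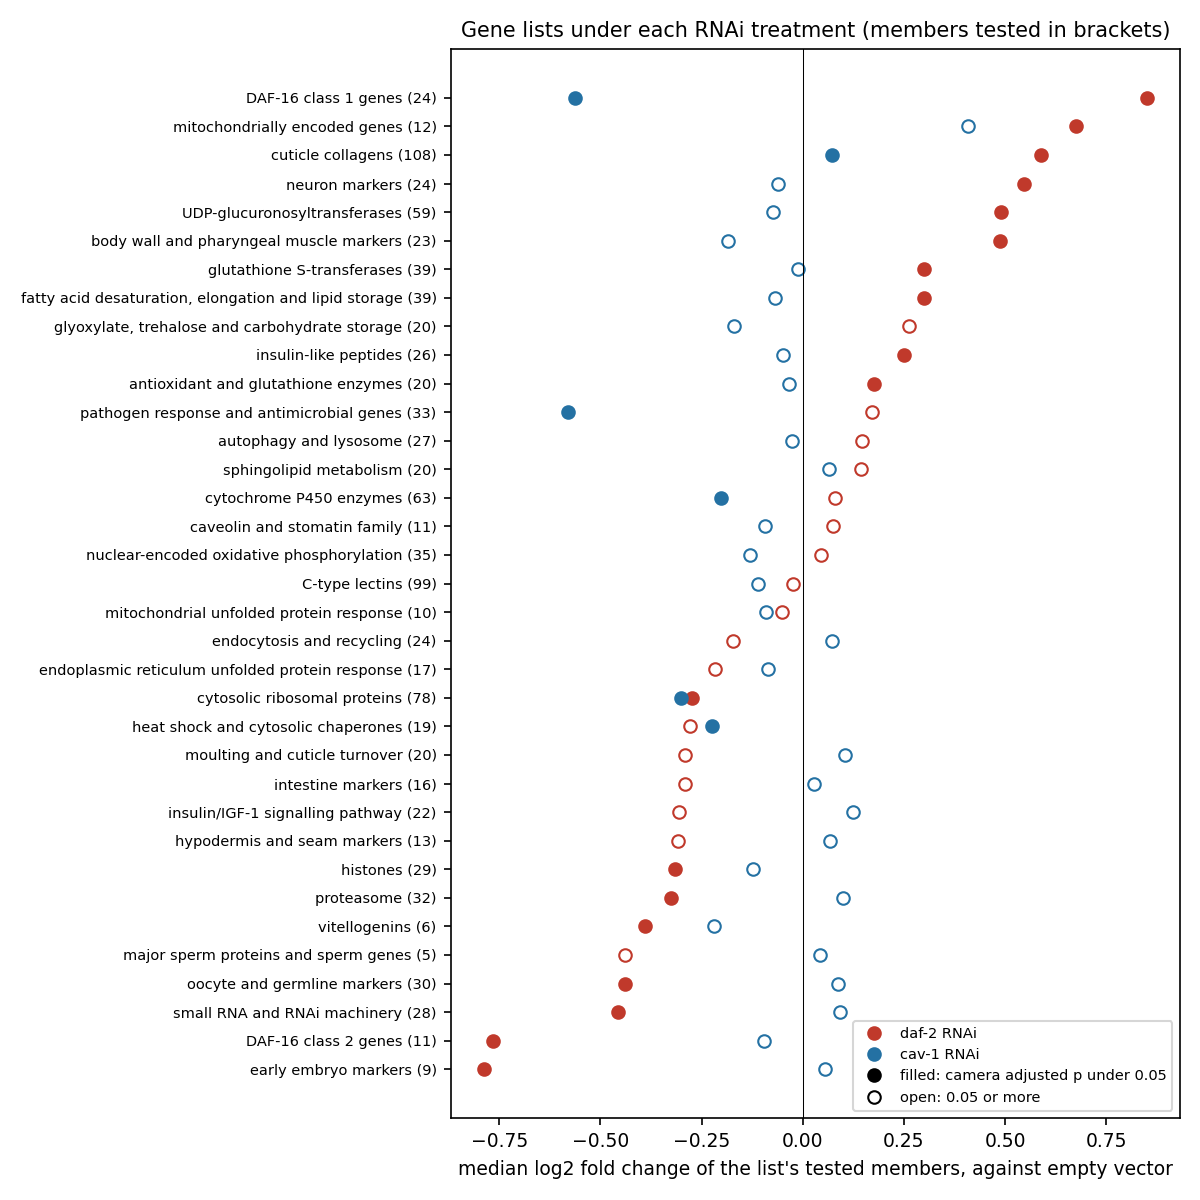
Median log2 fold change of the tested members of each of the 35 gene lists against empty vector, under daf-2 RNAi (red) and cav-1 RNAi (blue), with filled points where the camera adjusted p was under 0.05. DAF-16 class 1 genes lie at 0.85 under daf-2 RNAi and at -0.56 under cav-1 RNAi, and the lists whose sign depends on the scaling all lie within 0.07 of 0.

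cav-1 fell under both treatments in the blocked fit. As cav-1 was also the single gene called under cav-1 RNAi there, those calls cannot show how alike the responses were. In the authors' deposited results 17 genes were lower under both treatments (2.66 expected), 17 were higher under both (1.14 expected) and 12 were opposite, among 13827 genes. These expectations leave out that both comparisons share the empty vector libraries. Across 14378 genes the log2 fold changes of the treatments had a Pearson correlation of -0.0138 and a Spearman correlation of -0.114, while simulated unchanged groups sharing the same empty vector libraries gave a mean of 0.5. The covariance was -0.00227, against 0.0317 in the simulation, and 43.9% of genes had the same sign, against 66.6%. The simulation drew independent noise for each gene, without treatment effects or the length trends of the libraries. It therefore cannot show whether the responses were opposed. With empty vector 1 as the control of daf-2 RNAi 1 and empty vector 2 as that of cav-1 RNAi 2 the Pearson correlation was 0.106, and daf-2 RNAi 2 with cav-1 RNAi 1, each against the empty vector library of its own repeat, gave -0.322. In fits without the block the correlation was 0.656 without empty vector 1, 0.569 without empty vector 2, 0.292 without daf-2 RNAi 1 and -0.275 without daf-2 RNAi 2. With 1 empty vector library left, both fold changes carry the same part of the repeat difference. The values 0.656 and 0.569 therefore do not show how alike the responses were. Between repeats, the daf-2 RNAi fold changes correlated at 0.705 and the cav-1 RNAi fold changes at -0.0525.

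Compared with daf-2 RNAi, cav-1 RNAi worms had higher C32H11.4 (log2 4.79), dod-23 (4.003), clec-266 (3.52), F08G5.6 (3.45) and dod-22 (3.06), and lower D1086.9 (-6.21), ZK355.3 (-5.97), H39E23.3 (-5.14), Y51B9A.8 (-4.995) and ZK355.8 (-4.98). Standard errors ran from 0.26 (F08G5.6) to 0.48 (D1086.9). This contrast tests the difference between the treatments directly, and 1526 genes differed with the repeat block, 538 higher and 988 lower under cav-1 RNAi. Of 24 class 1 genes 18 were lower and 1 higher, by both adjustments, with a median of -1.37 (adjusted p = 4.90e-09, and adjusted p = 0.177 with an estimated correlation). Of 11 class 2 genes 5 were higher, or 6 over the list alone, with a median of 1.01 (adjusted p = 6.61e-05, and adjusted p = 0.177 with an estimated correlation). The collagens were lower (25 of 108 lower and 1 higher, or 40 and 3 over the list alone, median -0.52, adjusted p = 2.29e-08, and adjusted p = 0.383 with an estimated correlation), as were the fatty acid and lipid storage genes (12 of 39, or 15 over the list alone, median -0.31, adjusted p = 0.00107, and adjusted p = 0.177 with an estimated correlation). Muscle (median -0.70, adjusted p = 0.00134) and neuron markers (-0.66, 0.000248) were lower and early embryo markers (0.65, 0.000248) higher, with an adjusted p = 0.177 with an estimated correlation for each. Oocyte and germline markers were higher (0.60, 0.000518, and adjusted p = 0.631 with an estimated correlation). In all 18 lists passed, 7 up and 11 down, the others being the insulin-like peptides (median -0.42), pathogen response genes (-0.60), cytochrome P450 genes (-0.30), UDP-glucuronosyltransferases (-0.44), glutathione S-transferases (-0.26), the glyoxylate list (-0.32), the proteasome (0.42), moulting (0.52) and small RNA genes (0.49) and the histones (0.26). With the block the insulin pathway, endocytosis and antioxidant lists passed in addition (adjusted p = 0.0439, 0.0241 and 0.0480, against 0.0964, 0.0959 and 0.0561 without it), the histones no longer did (0.117 against 0.0476), and no list passed in either fit with an estimated correlation. With the length trend removed the insulin-like peptides (adjusted p = 0.3001), glutathione S-transferases (0.153), pathogen response genes (0.123), moulting genes (0.330) and small RNA genes (0.127) did not pass, and the ribosomal protein genes did (median 0.23, adjusted p = 0.0229). With size factors the glyoxylate list and the histones did not pass (adjusted p = 0.0530 each), and with no filter the glyoxylate (0.0766) and pathogen response lists (0.109) did not and the antioxidant list did (0.0494). In the fry test the C-type lectins passed without the block (adjusted p = 0.0343) and the sperm genes with it (adjusted p = 0.0451). The medians of the sphingolipid (-0.00) and ribosomal protein lists (-0.01) were above 0 with size factors.

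Without the block limma called 0 genes for this contrast. At an unadjusted p under 0.05 lay 827 genes without the block and 5219 with it, against 719 if no gene changed. Here too the unblocked 827 cannot be read against 719. The deposited DESeq2 results held 3487 at 0.05, of which 2262 were higher and 1225 lower under cav-1 RNAi. The balance of higher and lower genes depended on the scaling, at 1902 higher and 1191 lower with size factors, and the blocked count was 3078 and 3060 without empty vector 1 and 2, 998 without daf-2 RNAi 1, 68 without cav-1 RNAi 1, 4206 without cav-1 RNAi 2 and 3075 from the 4 libraries compared.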

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

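Chosen after the data were seen were voom, the length correction, the block combined with other settings, and list tests with size factors or with the block under fry or an estimated correlation. The edgeR and DESeq2 fits planned on counts were not run.

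Without the block, limma called 0 genes for both treatments against empty vector under every scaling, filter, pseudocount, voom, length and 4-library setting, and for cav-1 against daf-2 RNAi 7 with the length trend removed and 52 from 4 libraries. The block changed these counts to 1070, 1 and 1526, and the log2 fold changes that then passed were -1.63 for daf-2 and -2.55 for cav-1 under daf-2 RNAi and -5.34 for cav-1 under cav-1 RNAi. With the length trend also removed the cav-1 values were -2.58 and -5.26. With the block, the daf-2 RNAi count was 579 with the strict filter, where fewer genes were tested, and between 805 and 1211 under the other full-library settings. The cav-1 RNAi count was 6 with size factors, 2 with a pseudocount of 0.5, 2 with voom and 82 from 4 libraries, and the count for cav-1 against daf-2 RNAi was 3093 with size factors and 3075 from 4 libraries. The strict filter tested fewer genes and the fits from 4 libraries used fewer samples, but the causes of these shifts were not tested.

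Each library left out in turn gave 0 to 21 genes (698 to 2197 with the block) for daf-2 RNAi, 0 to 0 (0 to 402) for cav-1 RNAi and 0 to 59 (68 to 4206) for cav-1 against daf-2 RNAi. With the block the daf-2 RNAi count was 1780 without empty vector 1. The cav-1 RNAi count was 110 and 123 without empty vector 1 and 2 and 75 and 73 without daf-2 RNAi 1 and 2. The count for cav-1 against daf-2 RNAi was 3078 and 3060 without empty vector 1 and 2 and 998 without daf-2 RNAi 1. The log2 fold change of cav-1 ran from -5.91 to -4.74 (-5.94 to -4.74) under cav-1 RNAi and from -2.93 to -1.95 (-3.15 to -1.94) under daf-2 RNAi, and that of daf-2 under daf-2 RNAi from -2.68 to -0.57 (-2.51 to -0.53). With the block, daf-2 was at -2.16 without empty vector 1. cav-1 was at -2.69 and -2.18 under daf-2 RNAi without daf-2 RNAi 1 and 2, and under cav-1 RNAi at -5.32 and -5.33 without daf-2 RNAi 1 and 2 and at -4.97 without cav-1 RNAi 2. The correlation of the treatments ran from -0.275 to 0.656, was -0.322 for daf-2 RNAi 2 with cav-1 RNAi 1, each against the empty vector library of its own repeat, and counts of genes called alike under both were 0 in each of these fits without the block, 1 with the block on all libraries and 34 in the deposited DESeq2 results. Several values changed sign in some of these fits, with none past the threshold there. They were daf-2 under cav-1 RNAi (-0.75 to 1.37, with the block -0.23 to 0.85, at -0.12 without cav-1 RNAi 2), cav-2 under daf-2 RNAi (-0.72 to 0.56, with the block 0.35 without empty vector 1 and 0.0700 without daf-2 RNAi 2) and cav-1 RNAi (-0.81 to 0.47, with the block 0.25 without empty vector 1 and 0.24 without cav-1 RNAi 1), and under daf-2 RNAi rpn-2 (-1.17 to 0.33, with the block -0.53 to -0.25), rpn-1 (-1.18 to 0.37, -0.50 to -0.25), nduo-4 (-0.35 to 2.55, 0.07 to 2.13), nduo-1 (-0.34 to 1.66, 0.17 to 1.16), rme-2 (-1.58 to 0.45, -0.71 to -0.49), glh-2 (-1.63 to 0.53, -0.63 to -0.48), myo-1 (-0.97 to 3.29, 0.87 to 1.57) and ergo-1 (-1.47 to 0.52, -0.61 to -0.39), and rpl-29 under cav-1 RNAi (-1.41 to 0.37, -0.79 to -0.31). Of these, only daf-2 and cav-2 changed sign with the block. The other genes changed sign only without it, where leaving out a library leaves the repeats unbalanced. Part of the repeat difference then enters the fold change. The range of the correlation came from fits without the block as well. For daf-2 and cav-2, and for the counts above, the cause was not tested.

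Of 79 named genes called under daf-2 RNAi with the block, all kept their direction in each setting where they were tested, and 66 to 79 stayed past the threshold (57 of 63 with the strict filter). Of the 10 named for cav-1 against daf-2 RNAi, 6 stayed past it without cav-1 RNAi 1. The gene lists called were 18, 6 and 18 for the 3 contrasts in the order above, 0, 0 and 0 with an estimated correlation, 2, 0 and 6 with fry, 0, 0 and 0 with the block and an estimated correlation, and 1, 0 and 2 with the block and fry (the sperm list for daf-2 RNAi, and the sperm and fatty acid lists for cav-1 against daf-2 RNAi). They were 19, 6 and 18 with total-count scaling, 17, 6 and 16 with size factors, 16, 5 and 17 with no filter, and 15, 8 and 14 with the length trend removed. Each list whose camera call with the preset correlation was changed by these settings or by the block is named with its comparison. Total-count scaling and size factors moved the median of all genes by at most 0.065 on the log2 scale.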

Other observations

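Chosen after the results were seen were the genes of the deposited table named next, both transcript-length tests of the repeat difference, the germline and length tests of cav-1 under daf-2 RNAi, and the estimated-correlation test of the class 1 list. The other tests given here were fixed before their results were seen.

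In the authors' deposited comparison of cav-1 RNAi with empty vector, the largest rise was in nep-8 (log2 2.40, adjusted p = 1.56e-05), a gene of the neprilysin family of metallopeptidases, followed by F44G3.2 (1.92). After cav-1 itself (-4.73) the largest falls were in F48C1.9 (-2.11, adjusted p = 1.30e-08), cyp-14A3 (-1.99), comt-4 (-1.90), scl-11 (-1.85), thn-1 (-1.85) and the acyl-CoA synthetase gene acs-2 (-1.76). The antimicrobial peptide gene cnc-6 (-1.72), fipr-26 (-1.73), fipr-22 (-1.47) and nlp-34 (-1.64) were lower as well. Besides cav-1, none of these passed in the blocked limma fit.

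The 12 genes with opposite calls in the deposited results included ZK355.3 (4.67 under daf-2 RNAi and -1.45 under cav-1 RNAi), ZK355.8 (3.98 and -1.26), Y51B9A.8 (3.18 and -1.56), comt-4 (2.203 and -1.90), the saposin-like gene spp-12 (1.86 and -1.54) and ugt-27 (0.99 and -1.09). Genes lower under both included thn-1 (-2.54 and -1.85), dod-24 (-3.82 and -1.32), gba-2 (-4.12 and -1.28) and cyp-14A3 (-2.01 and -1.99), and genes higher under both included col-94 (2.56 and 1.40), col-93 (1.63 and 1.12), K10B2.2 (2.09 and 1.43) and Y49G5A.1 (2.93 and 1.64).

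The libraries of the 2 repeats differed in 5331 genes when split by repeat alone, and 0 was the highest count among the other splits. In each other split the repeat difference enters the residual, so those splits could call few genes and their counts say little about chance. Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many genes, and 10 splits are too few for a share under 0.05. The rise of the repeat difference with transcript length (rho 0.545 across genes) is consistent with a length-dependent difference in RNA quality or library preparation as part of it, but length is argued against as the whole of it, because the first component still separated the repeats with 56.1% of the variance after a length trend was removed. After that removal the median of the oocyte and germline markers was 0.75 higher in repeat 2 (95% interval over members 0.60 to 1.09, adjusted p = 9.45e-05, and adjusted p = 0.799 with an estimated correlation). More germline RNA in repeat 2 and differences in age or growth may contribute and stay open, as the medians of ribosomal protein genes (0.79), intestine markers (0.65) and collagens (0.55) lay above 0 as well, with adjusted p = 0.799, 0.735 and 0.735 with an estimated correlation.

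The fall of cav-1 under daf-2 RNAi (-2.55) was weighed against less germline tissue, since oocyte and germline markers also lay lower. Their median was -0.44 (95% interval over members -0.51 to -0.38), at -0.47 in repeat 1 and -0.41 in repeat 2. This lies far from the fall of cav-1, which argues against an even loss of germline tissue as the whole of it. A loss confined to part of the germline was not tested and stays open. The early embryo list lay lower than these markers, with a median of -0.79. Genes of 500 to 1000 nt, the class holding cav-1 (925 nt), had a median of 0.06 under daf-2 RNAi. A length trend of that size is too small to account for the fall. Its removal could therefore change little, and left cav-1 at -2.58. Bacteria carrying the cav-1 construct on the daf-2 RNAi plates would move the other genes called under cav-1 RNAi the same way, and 49 of 80 such genes in the deposited results did (61.25%, exact 95% interval 49.7% to 71.9%). That share cannot be told apart from the one the shared empty vector libraries alone might give, so mixed bacteria and an effect of daf-2 RNAi on cav-1 both remain open, and the latter is a hypothesis that a separate measurement of cav-1 would test.

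The lower level of the class 1 list under cav-1 RNAi was weighed in the same way. Medians of all genes by length class ran only from -0.11 to 0.10 under cav-1 RNAi, too small a trend to account for it. Removal of the trend could therefore change little, and left the list median at -0.56 (95% interval -0.70 to -0.37). The higher of the list's repeat medians was -0.53, with 19 of 24 genes below 0 in both repeats. This argues against a single repeat as its source. Chance values shared by correlated genes in the empty vector libraries stay open. The list did not pass with an estimated correlation (adjusted p = 0.190), but with 3 residual degrees of freedom that test cannot decide. Single members did not all reverse, as these values, chosen after they were seen, show. In the deposited results sod-3 was at 0.19 and mtl-1 at -0.48 under cav-1 RNAi (DESeq2 adjusted p = 0.999 each). In the limma fits sodh-1 lay lower under both treatments. The list as a whole may lie lower under cav-1 RNAi, opposite to its direction under daf-2 RNAi, but with 2 samples per group this is a hypothesis only.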
